A study of Mus musculus with 8 samples.

How the data were processed

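RNA from mouse neurosphere cells was measured on 8 short-oligonucleotide arrays, 2 for each of 4 groups: untreated, AzaC, TSA and AzaC/TSA. The deposited values are intensity on a linear scale, 1 value per probe set and array, and the values themselves show that the authors had scaled each array to the same 2%-trimmed mean, 200.1. The probe sets carry Affymetrix-type names. The upstream software and its settings are not given in the sources used here. Values ran from 0.1 to 26044.5.

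The file held 12488 probe sets. The 66 control probe sets were left out after scaling. Values under 10% of the trimmed mean, a signal of 20, were raised to that floor, and the floored values were log2-transformed. A change whose lower group had any array under the floor is a lower bound of its size (at least), and values of single genes that rest on such arrays are marked. Probe sets were tested when at least 2 of the 8 arrays reached 25% of the trimmed mean, a signal of 50, which left 7987 probe sets (64.3%). The array annotation gave a single gene symbol to 10855 probe sets, several symbols to 396 and none to 1237. Of the gene identifiers behind the single symbols, 10839 probe sets had theirs in the reference annotation. The tested probe sets represented 6011 genes, and 1044 genes had several. Where 1 probe set per gene was needed, the one with the highest mean over all 8 arrays was used. Probe sets without a single symbol (759 of those tested) were counted but not named.

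Log2 signals were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 1 mean per group over all 8 arrays. The fit had 4 residual degrees of freedom and a prior of 4.93. Each contrast was tested two-sided, p-values were adjusted by Benjamini-Hochberg over the 7987 probe sets, and the threshold was an adjusted p of 0.05. Every p-value rests on 2 arrays per group. The 6 contrasts were AzaC, TSA and AzaC/TSA against untreated, AzaC/TSA against AzaC, AzaC/TSA against TSA, and the AzaC by TSA interaction. The sample titles number the experiments 1 and 2, so arrays of the same number share an experiment. As a check of this pairing, the deviations of the arrays from their group means correlated between groups by experiment with r from 0.203 to 0.411 over the 6 pairs of groups. The experiment as a block (3 residual degrees of freedom, prior 6.71) was an alternative, and its counts of probe sets and of list members stand beside those reported.

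Gene lists, with 742 genes in 22 lists, were fixed before the data were examined. They covered neural stem and progenitor cells, neurons, astrocytes, oligodendrocyte lineage, blood cells and their progenitors, microglia and macrophages, endothelial cells and pericytes, fibroblasts and meninges, muscle, imprinted genes, germ line and testis, interferon response, MHC class I and antigen processing, p53 targets and growth arrest, DNA replication and S phase, mitosis, chromatin and DNA methylation enzymes, histones, apoptosis and the Bcl2 family, stress response and metallothioneins, cholesterol synthesis, and Hox genes. The array named 588 of the genes and 379 were tested. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists within a contrast. camera with an estimated correlation and fry were run as alternatives. Members past the threshold were counted over all probe sets and also adjusted over the list alone.

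Named genes followed a rule fixed before the data were examined. For each comparison with untreated these were the 10 largest rises and 10 largest falls among genes past the threshold that moved the same way in both experiments, and for the other contrasts the 5 largest each way. Where fewer than 5 passed, the 5 of smallest unadjusted p were taken and are said not to pass. Up to 4 members of each list in order of p, and Dnmt1, Dnmt3a, Dnmt3b, Hdac1, Hdac2, Cdkn1a, H1f0, Bcl2, Nes, Gfap, Tubb3, Ptprc, Cd34 and Kit, were added. Further list members are named from the list counts.

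Alternatives changed 1 choice at a time: quantile normalization, median centring or no scaling; a floor of 2.5% or 20%, or an offset in its place; no filter or a filter at 50%; no intensity trend; robust eBayes; only the groups compared; the replicate block; and each array left out in turn. Leaving out an array left its group with 1, which was assumed to vary like the others. That group then came from 1 experiment only, so its contrasts also carried the difference between experiments. The fit was tested on simulated data with the same spread, with 200 of 7987 probe sets changed and 10 simulations. The changed probe sets were drawn only from those with a mean untreated signal above 4 times the floor. For TSA against untreated it recovered 9.55% of the changes of 1, 77.0% of those of 2 and 96.8% of those of 4 on the log2 scale, with 5.36% of its calls false. All 10 lists of 30 genes shifted by a log2 of 1 were called, and 0 of 200 unchanged lists. The noise was drawn independently for each gene and array, without a difference between experiments. The simulations therefore cannot show how often lists of correlated genes are called falsely. Overlaps were set against 100 simulations of unchanged groups that share the untreated arrays, with the same independent noise. Comparisons of TSA with AzaC, of AzaC averaged over TSA, of experiment 2 with experiment 1, and of the TSA effect between experiments were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 drew the figures.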

Results

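Neurosphere cells, which are cultured neural stem and progenitor cells, came from individually isolated forebrains of mouse embryos at embryonic day 14.5 that carried a bcl2 transgene. They were left untreated or exposed for 2 days to 500 nM AzaC (5-aza-2'-deoxycytidine, an inhibitor of DNA methyltransferases), to 150 nM TSA (trichostatin A, an inhibitor of histone deacetylases), or to both (AzaC/TSA). Each of the 4 groups had 2 arrays, 1 from each of 2 independent experiments. The median signal per array ran from 59.2 to 72.7, and 53.1% to 58.3% of probe sets reached the filter signal. The number of arrays limits the precision: the median standard error of a log2 change between groups was 0.41, with a 95% half-width of 0.93. With the experiment as a block these were 0.35 and 0.79. The ratio of 5' to 3' control signals for actin, a sign of RNA integrity, ran from 0.29 (AzaC/TSA 1) to 0.471 (AzaC 1). Pairs of arrays that shared TSA exposure correlated with r from 0.895 to 0.955 across probe sets (12 pairs). Among them the pairs of the same group, each from different experiments, gave 0.8965 to 0.92 (4 pairs). The pairs of the same experiment that differed in AzaC were all higher, with 0.928 to 0.955. Pairs that differed in TSA exposure gave 0.813 to 0.875 (16 pairs).

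The comparison of TSA with untreated cells asked which transcripts differ after histone deacetylase inhibition. Genes of cell division fell: Mki67, a marker of cycling cells, was at least 43.6-fold lower (log2 change -5.45, SE 0.35, n = 2 arrays per group, adjusted p = 0.000219), and Cdc20, an activator of the anaphase-promoting complex, was 24.9-fold lower (-4.64, SE 0.30, adjusted p = 0.000219). Top2a, the topoisomerase that untangles chromosomes, fell at least 31.9-fold. The other 7 of the 10 largest falls were Kif20a (-4.60), Pclaf (-4.59), Mcm5 (-4.31), Cdk1 (-4.29), and Plk4 (-4.22), Aurkb (-4.19) and Kif11 (-4.17), the last 3 of them falls of at least that size. Among the 10 largest rises were Clu (clusterin, a secreted chaperone), 23.7-fold higher (4.57, SE 0.28, adjusted p = 0.000219), Scg2 (secretogranin II, of secretory granules), at least 19.8-fold higher (4.31, SE 0.48), Snap25 (a synaptic fusion protein), at least 19.7-fold higher (4.30, SE 0.49), and the immediate early gene Fos, 13.6-fold higher (3.77, SE 0.36). Anxa2 (at least 4.57), Lcn2 (at least 4.08), Akr1b8 (3.99), Txnip (3.86), Chgb (3.81) and Sat1 (3.58) completed them. A second probe set of Lcn2 did not pass and lay in the other direction.

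**Figure D1:**
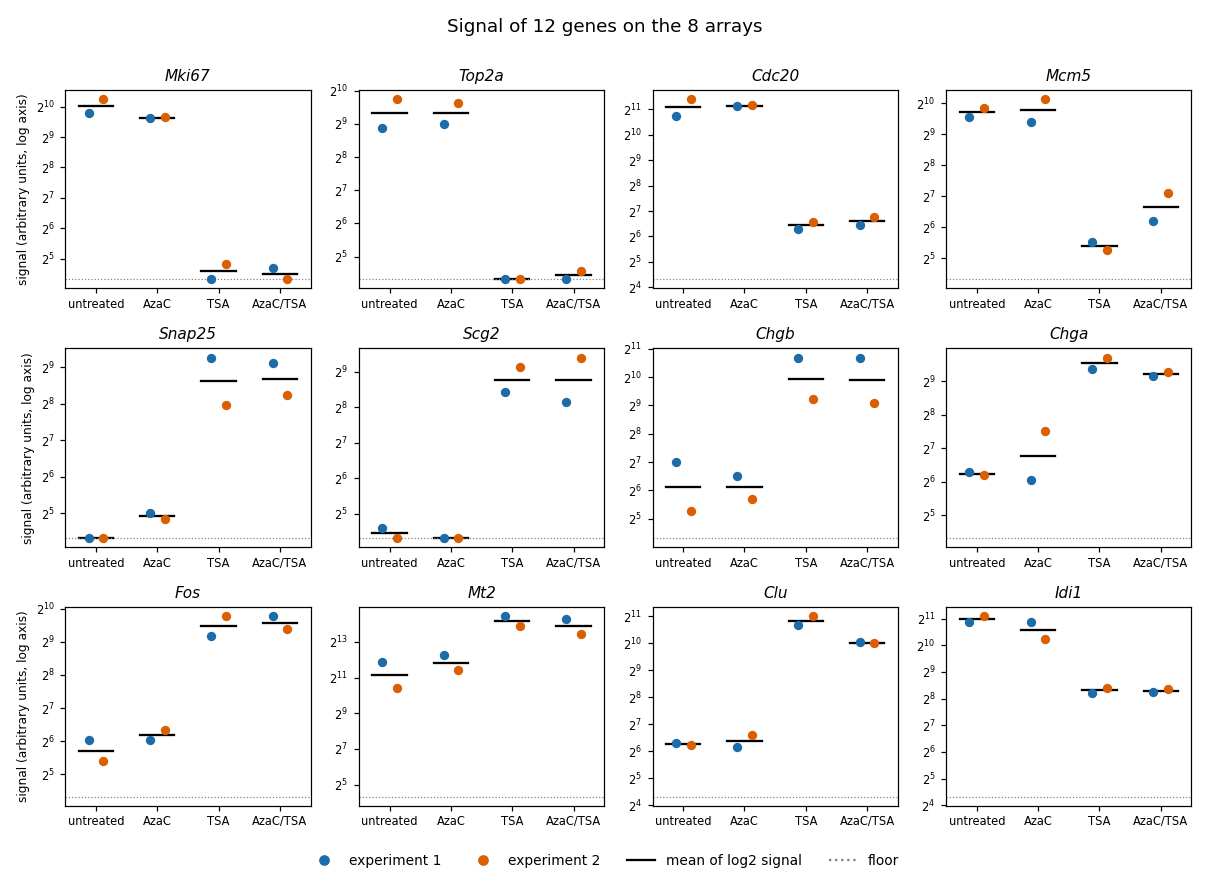
Signal of 12 genes (log axis, arbitrary units) on the 8 arrays by group, with points coloured by experiment, a black bar at the mean of the log2 signals and a dotted line at the floor of 20. Mki67 lay between 787 and 1226 on the 4 arrays without TSA and at or under 28.4 on the 4 arrays with it.

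In all, limma called 401 of 7987 probe sets, 167 higher and 234 lower, for 147 and 208 named genes, and all 401 moved the same way in both experiments. The median log2 change of the calls was 1.82 upward and -2.13 downward, and 398 exceeded 2-fold. With the experiment as a block the count was 971 (447 higher and 524 lower), which included all 401. Single arrays weighed on the count, which was 125 without untreated 1, 56 without untreated 2, 99 without TSA 1 and 67 without TSA 2. Of the 45 named calls, 18 passed in each of 20 alternatives, among them Mki67, Cdc20, Top2a, Clu, Scg2, Snap25, Fos, Rrm2, H2ax and Idi1. The other 27 were lost in at least 1, with 26 lost without TSA 2, 24 without untreated 2, 21 without TSA 1, 16 without untreated 1 and 4 to 6 without each other array, and the largest adjusted p was 0.281 (Gas1). S100b, H2-K1, Ddit4, Gas1 and Cycs passed in the fewest: each was lost without the filter or the intensity trend, with only the groups compared, and without untreated 1, AzaC 2, either TSA array or either AzaC/TSA array. The largest rise of all, at least 6.78, belonged to a probe set with no gene symbol.

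Of 35 tested mitosis genes, 30 fell with TSA and 0 rose, and the list median was -2.92. Besides those above, Birc5 (-3.94, at least), Aurka (-3.90, at least), Ccna2 (-3.25), Ccnb2 (-2.89) and Plk1 (-2.68) fell, while Ube2c (-1.58, at least), Bub3 (-0.77), Pttg1 (-0.51), Foxm1 (-0.48) and Incenp (-0.40) did not pass. Adjusted over the list alone 32 fell, and with the block 31. camera gave an adjusted p of 2.4e-33, against an adjusted p = 0.19 with an estimated correlation. In the list of DNA replication and S phase, 10 of 35 members fell and 0 rose (median -1.38), with 22 falling adjusted over the list alone and 19 with the block. They included the ribonucleotide reductase subunits Rrm2 (-3.36) and Rrm1 (-2.85), the licensing factor Cdc6 (-3.35, at least), thymidine kinase Tk1 (-3.04) and the helicase subunits Mcm4 (-2.30) and Mcm7 (-2.04). camera gave an adjusted p of 1.2e-14, against an adjusted p = 0.29 with an estimated correlation. Cholesterol synthesis also shifted downward (median -0.94; 5 of 15 fell, 7 adjusted over the list alone and 7 with the block), with Idi1 (-2.68, SE 0.28), Cyp51 (-2.15), Lss (-2.11), Hmgcs1 (-1.73) and Nsdhl (-1.58). Its camera adjusted p was 4.7e-05, and adjusted p = 0.30 with an estimated correlation.

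Neuronal genes shifted upward with TSA: 9 of 25 rose and 0 fell, and the median was 1.02. Adjusted over the list alone 11 rose and 1 fell, and with the block 9 rose and 1 fell. Besides Scg2, Snap25 and Chgb, these were Chga (3.30), the synaptic vesicle protein Syp (2.38, at least), Reln (2.81), Calb2 (2.27), Uchl1 (1.92) and Mapt (1.02). The widely used neuronal markers Tubb3 (-0.81), Map2 (-0.27) and Dcx (0.39) did not pass. A second, dimmer probe set of Tubb3 lay in the other direction. Its signals for experiments 1 and 2 were 17.5 and 76.8 untreated, and 81.3 and 86.1 with TSA. Both Tubb3 probe sets and that of Chgb are by name of the family kind, which can cross-hybridise with related genes. For this list camera gave an adjusted p of 3.2e-05, against an adjusted p = 0.19 with an estimated correlation. In the list of stress response and metallothioneins 8 of 31 rose and 0 fell (median 0.73), with 10 rising adjusted over the list alone and 11 with the block. Fos, the metal-binding proteins Mt2 (3.02, SE 0.51) and Mt1 (2.61), the heat shock protein Hspa1b (2.36), Egr1 (2.17), Ier2 (2.0), Ddit3 (1.74) and Gclc (1.6) were those members. Its camera adjusted p was 3.2e-05, and adjusted p = 0.29 with an estimated correlation.

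Other than the neuronal list, no list of cell identity passed camera with TSA. In the list of neural stem and progenitor cells 1 of 21 members fell, Fabp7 (-2.63, SE 0.43), a fatty acid binding protein of radial glia, also adjusted over the list alone (with the block 1 rose and 2 fell), while Nes (-0.63), Sox2 (-0.31) and Hes1 (0.28) did not pass (median -0.02; camera adjusted p = 0.84). Among 12 astrocyte genes Clu rose and S100b (-1.63, passing in 6 of 20 alternatives) fell, and adjusted over the list alone 2 rose and 2 fell, with the block 1 and 2 (camera adjusted p = 0.86). Of 7 oligodendrocyte lineage genes 0 passed, and 1 fell adjusted over the list alone or with the block (0.84). For markers of other cell types, 0 of 16 genes of blood cells and their progenitors passed (0.84), 0 of 3 of endothelial cells and pericytes (0.93), 0 of 13 of muscle (0.33), and 0 of 12 of fibroblasts and meninges (0.85), where 1 rose and 1 fell adjusted over the list alone, and 2 rose and 1 fell with the block. Cd68, a lysosomal protein of macrophages, rose (2.69, SE 0.56) as 1 of 5 genes of microglia and macrophages, also adjusted over the list alone and with the block (0.84). Of 10 Hox genes and 8 genes of germ line and testis 0 passed (0.84 each), as did 0 of 10 of the interferon response (0.32), where 3 rose with the block. In the other lists of this paragraph with 0 members past the threshold, the block also gave 0. The median and the mean differed in sign in the astrocyte, oligodendrocyte, fibroblast and microglia lists.

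Of 19 imprinted genes 1 rose with TSA, the growth factor Igf2 (3.21, SE 0.53), also adjusted over the list alone, and with the block 1 rose and 3 fell (camera adjusted p = 0.84). Of 15 genes of MHC class I and antigen processing H2-K1 (1.72, passing in 8 of 20 alternatives), a class I heavy chain, rose, and adjusted over the list alone 2 rose and 1 fell, with the block 4 and 1 (0.22). The H2-K1 probe set is also of the family kind. Of 22 p53 targets and growth arrest genes Ddit4 (1.21, passing in 8 of 20) rose and Gas1 (-1.78, in 6 of 20) fell, and adjusted over the list alone 2 rose and 2 fell, with the block 2 and 3 (0.14). Of 19 genes of apoptosis and the Bcl2 family Cycs (-1.26, passing in 8 of 20), cytochrome c, fell, also adjusted over the list alone and with the block (0.84). Among 39 chromatin and DNA methylation enzymes Hdac6 (1.38) rose and 6 fell, namely Cbx5 (-2.33), Uhrf1 (-2.02), Mbd3 (-1.43), Smarcb1 (-1.26), Bmi1 (-1.19) and Trim28 (-1.12), and adjusted over the list alone or with the block 1 rose and 8 fell (0.14). Of 8 histone genes the variant H2ax (-2.45, SE 0.26) fell, and 2 fell adjusted over the list alone or with the block (0.29). In the imprinted and apoptosis lists the median and the mean differed in sign. Without untreated 2 the MHC class I list passed upward (median 0.76), and without TSA 2 the p53 list did (0.59). Each of these fits leaves a group with 1 array of a single experiment, and so carries the difference between experiments. For these lists and this contrast camera gave an adjusted p = 0.82 and an adjusted p = 0.34 with an estimated correlation. fry, which asks whether a list changed at all and not whether it differs from other genes, passed the chromatin (0.029) and histone (0.03) lists downward, for which camera gave an adjusted p = 0.39 and an adjusted p = 0.49 with an estimated correlation.

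**Figure D2:**
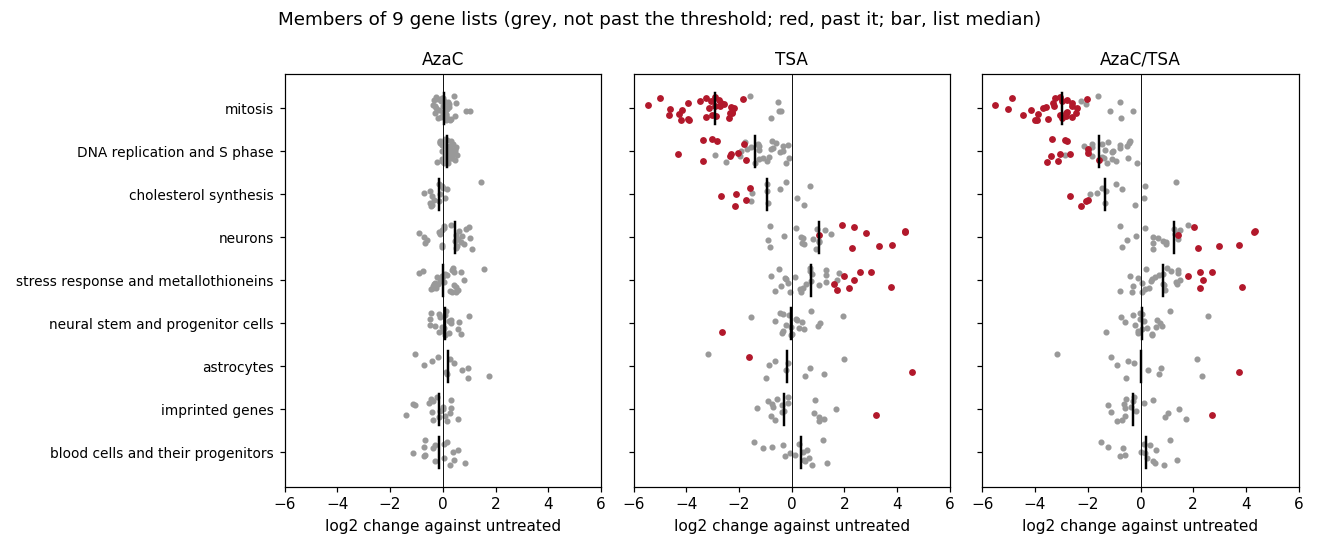
Log2 change against untreated of each tested member of 9 lists for AzaC, TSA and AzaC/TSA, red where past the threshold and grey otherwise, with a bar at the list median. With TSA 30 of 35 mitosis genes and with AzaC/TSA 28 of 35 were past the threshold, all below 0, and with AzaC 0 of 35.

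AzaC/TSA was compared with untreated cells to ask what both inhibitors together do. The largest changes included genes named above for TSA: Mki67 was at least 46.1-fold lower (-5.53, SE 0.35, adjusted p = 0.00045), Kif20a at least 32.9-fold lower (-5.04), Top2a at least 29.2-fold lower (-4.87) and Cdc20 22.2-fold lower (-4.47). Snap25 was at least 20.5-fold higher (4.36, SE 0.49, adjusted p = 0.00361), Scg2 at least 19.8-fold higher (4.30, SE 0.48), Fos 14.6-fold higher (3.87, SE 0.36) and Clu 13.5-fold higher (3.75, SE 0.28, adjusted p = 0.000591). The other large rises were the actin-severing protein Gsn (at least 4.48, SE 0.90, adjusted p = 0.0327), Rnase4 (at least 4.36), Anxa2 (at least 4.17), Akr1b8 (3.78), Chgb (3.75) and Resp18 (3.36). The other large falls were Cdk1 (-3.90) and, each a fall of at least that size, Pclaf (-4.83), Kif11 (-4.17), Aurkb (-4.02), Pygm (-3.93, muscle glycogen phosphorylase) and Aurka (-3.92).

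Of 35 mitosis genes 28 fell and 0 rose (median -2.99; 33 adjusted over the list alone and 31 with the block; camera adjusted p 1e-37), and of 35 genes of DNA replication and S phase 11 fell (median -1.59; 25 adjusted over the list alone and 22 with the block; 5.5e-19). Neuronal genes rose in 7 of 25 (median 1.27; 10 rose and 1 fell adjusted over the list alone, and 9 rose with the block; 2.4e-06), with Chga (2.98), Calb2 (2.19), Syp (at least 2.04) and Mapt (1.42) beside those above. Stress and metallothionein genes rose in 6 of 31 (median 0.86; 12 adjusted over the list alone and 10 with the block; 2.4e-06), among them Mt2 (2.73), Hspa1b (2.35), Egr1 (2.26) and Mt1 (2.25). Cholesterol synthesis genes fell in 4 of 15 (median -1.35; 10 adjusted over the list alone and 8 with the block; 2.4e-06), namely Idi1 (-2.69), Cyp51 (-2.28), Fdps (-2.07) and Hmgcs1 (-1.99). Further lists passed with few members: p53 targets and growth arrest upward (median 0.45; 0 of 22 passed, and adjusted over the list alone 1 rose and 1 fell, with the block 5 and 1; camera adjusted p = 0.014), and histones downward (median -0.73; H2ax, -2.63, was 1 of 8, also adjusted over the list alone, and 2 fell with the block; 0.022). Each of these 7 lists had an adjusted p = 0.16 with an estimated correlation. The p53 list also lost its call without untreated 1 or AzaC/TSA 1, and the histone list without AzaC/TSA 1, with medians over all alternatives from 0.38 to 0.61 and from -0.97 to -0.49. Without untreated 2 the MHC class I list passed upward (median 0.88), in a fit that also carries the difference between experiments. On all arrays camera gave this list an adjusted p = 0.64 with an estimated correlation. By fry the astrocyte list passed upward (median 0.02, 0.038; 1 of 12 rose, adjusted over the list alone or with the block 2 rose and 1 fell) and the chromatin list downward (-0.20, 0.026), against an adjusted p = 0.81 and an adjusted p = 0.37 for camera with an estimated correlation. Among chromatin and DNA methylation enzymes 5 of 39 fell (8 adjusted over the list alone and 8 with the block; camera adjusted p = 0.12): Uhrf1 (-2.49), which brings the maintenance methyltransferase to DNA, Cbx5 (-1.72), Dnmt1 itself (-1.61), Mbd3 (-1.36) and Trim28 (-1.27).

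limma called 249 probe sets, 103 higher and 146 lower, for 87 and 127 named genes, with medians of 2.25 and -2.50, and all 249 moved the same way in both experiments. With the experiment as a block there were 746 (350 higher and 396 lower), including all 249. The count was 102 without untreated 1, 14 without untreated 2, 66 without AzaC/TSA 1 and 92 without AzaC/TSA 2. Of 40 named calls, 10 passed in each of 20 alternatives, among them Mki67, Kif20a, Top2a, Cdc20, Fos and Clu. The other 30 were all lost without untreated 2, 19 of them without AzaC/TSA 1, 17 without AzaC/TSA 2, 14 without untreated 1, and 2 to 4 without each AzaC or TSA array, with adjusted p up to 0.244 (Gsn). Of the genes given here Pygm (8 of 20), Trim28 (9) and Anxa2 (10) passed in the fewest.

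The calls of TSA and AzaC/TSA overlapped: 91 probe sets were higher in both and 130 lower in both, with 0 in opposite directions. Independent lists of these sizes would share 2.15 and 4.28. Simulated unchanged groups against the same untreated arrays shared 0. Groups without any change have hardly any calls to share, so this 0 cannot show how much overlap the shared untreated arrays bring. Across probe sets, which are not independent replicates, the log2 changes correlated with r = 0.862. Simulated unchanged groups, which share the untreated arrays, gave 0.501. With a single treated and untreated array per treatment, each treatment from a different experiment, no array was shared and r was 0.514 and 0.512. For these values 0.501 is no reference, since it arises from the shared arrays. For AzaC and TSA r was 0.223, with a covariance of 0.0887 against 0.109 for simulated unchanged groups, and r was -0.0154 and 0.0202 where each treatment was set against a different untreated array. Part of the overlap can come from the shared untreated arrays. Over the 401 TSA calls the median ratio of the AzaC/TSA change to the TSA change was 0.883. These probe sets were chosen for their TSA change on the same arrays, so a smaller AzaC/TSA change can arise from the selection alone. No weakening of the TSA response by AzaC is read from it.

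**Figure D3:**
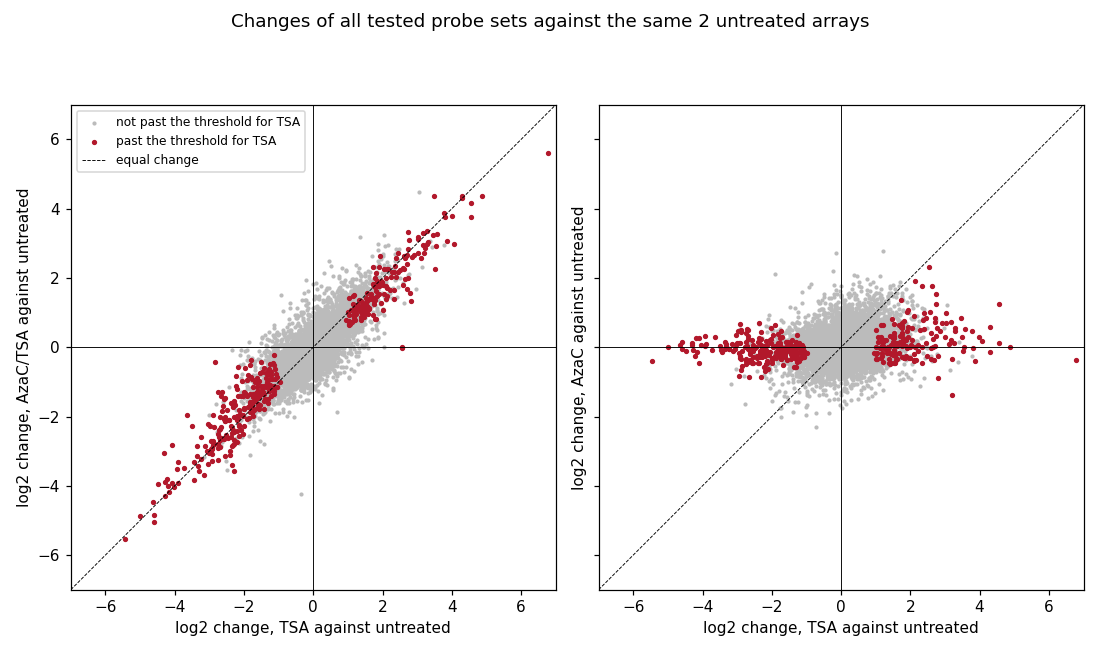
Log2 change of each tested probe set with AzaC/TSA (left) and with AzaC (right) plotted over that with TSA, all against the same 2 untreated arrays, red where past the threshold for TSA and with a dashed line at equal change. Across all points r was 0.862 on the left and 0.223 on the right, and where the treatments were set against different untreated arrays it was 0.514 and 0.512 on the left and -0.0154 and 0.0202 on the right.

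The AzaC comparison asked what inhibiting DNA methylation alone does. No named gene passed: the changes of Mki67 (-0.38), Snap25 (at least 0.60) and Clu (0.12), large with TSA, did not pass with AzaC, and limma called 0 of 7987 probe sets (smallest adjusted p 1). At an unadjusted p under 0.05 there were 175, fewer than the 399 that chance gives. The genes of smallest p, none of which passed, were Cd4 (at least 2.32, SE 0.46), Sult4a1 (at least 1.77), Ciapin1 (at least 1.92), Nipsnap1 (1.84) and Tmem183a (1.17) on the higher side. On the lower side were Krtap5-1 (-1.40), Cherp (-1.68), Mzf1 (-1.88, at least), Ighd (-1.76, at least) and Pip4p2 (-0.94). Of the 22 lists 0 passed camera and 0 members passed, also adjusted over the list alone and with the block. Neurons (median 0.46), imprinted genes (-0.16), DNA replication (0.17) and cholesterol synthesis (-0.14) had the smallest camera adjusted p, 0.19, while mitosis (0.04) had 0.67. Single arrays made list calls: without untreated 2, DNA replication (median 0.39) and mitosis (0.30) passed upward. Without AzaC 1, DNA replication passed upward (0.41) and cholesterol synthesis downward (-0.60). Each of these fits leaves a group with 1 array of a single experiment, and so carries the difference between experiments. With an estimated correlation the smallest adjusted p of the 22 lists was adjusted p = 0.75. With the experiment as a block limma still called 0, with 328 at an unadjusted p under 0.05. The median half-width of the 95% interval was 0.93 on the log2 scale without the block and 0.79 with it. In data simulated with the spread of the fit without the block, the AzaC comparison recovered 10% of changes of 1 and 78.1% of changes of 2. The changed probe sets lay well above the floor in untreated cells. Recovery of rises from near the floor was therefore not measured. Median centring moved the median of all probe sets for this comparison from 0.027 to -0.13, and left the count at 0.

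Adding TSA to AzaC, read from AzaC/TSA against AzaC, lowered mitosis and DNA replication genes. Kif20a, a kinesin of cytokinesis, was at least 36.9-fold lower (-5.21, SE 0.37, adjusted p = 0.000613), followed by Mki67 (-5.14), Top2a (-4.87) and Pclaf (-4.77), all 3 of them falls of at least that size, and Cdc20 (-4.54). Scg2 was at least 21.8-fold higher (4.45, SE 0.48, adjusted p = 0.00311) and Igf2 17.3-fold higher (4.11, SE 0.53, adjusted p = 0.00584), with Rnase4 (4.08), Chgb (3.78) and Snap25 (3.76) next. Mitosis genes fell in 27 of 35 (median -2.99; 34 adjusted over the list alone and 33 with the block; camera adjusted p 1.8e-38) and DNA replication genes in 14 of 35 (median -1.99; 26 adjusted over the list alone and 23 with the block; 2.8e-21). Cholesterol synthesis fell in 4 of 15 (median -0.88; 7 adjusted over the list alone and 7 with the block; 3.3e-05). Neuronal genes rose in 4 of 25 (median 0.93; 9 adjusted over the list alone and 9 with the block; 0.00011), and stress genes in 5 of 31 (median 0.62; adjusted over the list alone 9 rose and 1 fell, with the block 10 and 1; 5.5e-06). The list of p53 targets and growth arrest passed upward (0.59; adjusted p = 0.0036) with 0 of 22 members past the threshold, and adjusted over the list alone 4 rose and 1 fell, with the block 5 rose. With an estimated correlation the mitosis, replication, neuronal and p53 lists had an adjusted p = 0.15, the stress list an adjusted p = 0.18 and cholesterol synthesis an adjusted p = 0.23. Uhrf1 (-3.06), Dnmt1 (-1.66), Mbd3 (-1.40) and Trim28 (-1.34) fell among 39 chromatin enzymes (7 adjusted over the list alone and 9 with the block; camera adjusted p = 0.27). The MHC class I list passed upward without untreated 1 (median 0.61, adjusted p = 0.045), untreated 2 (0.61, adjusted p = 0.046) or AzaC 2 (0.82, adjusted p = 0.022), and the histone list downward with quantile normalization (-0.61, adjusted p = 0.049). For these lists camera gave an adjusted p = 0.76 and an adjusted p = 0.24 with an estimated correlation. By fry the chromatin (0.034) and histone (0.018; 1 of 8 fell, also adjusted over the list alone, and 2 with the block) lists passed downward, against an adjusted p = 0.58 and an adjusted p = 0.24 for camera with an estimated correlation.

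For this contrast limma called 223 probe sets, 89 higher and 134 lower, all in the same direction in both experiments, and with the experiment as a block 744 (359 higher and 385 lower), including all 223. Median centring turned the balance to 116 higher and 104 lower. The count was 135 without untreated 1, 135 without untreated 2, 72 without AzaC 1, 48 without AzaC 2, 61 without AzaC/TSA 1 and 88 without AzaC/TSA 2. Of 30 named calls 11 passed in each of 20 alternatives, among them Kif20a, Mki67, Top2a, Pclaf, Cdc20, Scg2, Clu and Fos. The other 19 were lost in at least 1, with 17 lost without AzaC 2, 15 without AzaC/TSA 1, 11 without AzaC/TSA 2, 10 without AzaC 1, 7 without each untreated array, 2 without TSA 1 and 3 without TSA 2, and adjusted p up to 0.183 (Chgb). Trim28 passed in 10 of 20, the fewest of the genes given here.

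Adding AzaC to TSA, read from AzaC/TSA against TSA, gave no gene past the threshold. Clu (-0.82, SE 0.28) and the radial glia gene Fabp7 (1.33, SE 0.43) were among the list members of smallest p, and neither passed. limma called 0 of 7987 probe sets (smallest adjusted p 0.376), with 185 at an unadjusted p under 0.05, and with the experiment as a block 0, with 344. On the higher side the smallest p belonged to Myt1 (at least 2.02), Repin1 (2.42), Fgd1 (at least 1.62), Dynlrb1 (0.91) and Pspn (2.46), and on the lower side to Cd4 (-2.56), Reg2 (-2.59), Ascl2 (-1.93), Uba7 (-1.62) and Rnf10 (-1.20). Those of Cd4, Reg2, Ascl2 and Uba7 are at least that size. Of the 22 lists 0 passed (smallest camera adjusted p 0.074). With the block, the neural stem and progenitor list passed upward (median 0.36, adjusted p = 0.037), with 0 of 21 members past the threshold. With an estimated correlation its value was an adjusted p = 0.73, and no list had a smaller one. It also passed without TSA 1 (0.36, adjusted p = 0.034) and without AzaC/TSA 2 (0.61, adjusted p = 0.00089). Without AzaC/TSA 2, the lists of microglia and macrophages (-0.93) and of DNA replication and S phase (-0.22) passed downward (adjusted p = 0.037 each).

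The interaction asked whether AzaC acted differently in the presence of TSA. No gene passed, and Cd4, a T cell coreceptor, came closest (-4.88, SE 0.65, adjusted p = 0.29). Next on the lower side were Reg2 (-3.62), Chst3 (-2.70), Ciapin1 (-2.57) and Uba7 (-2.31), and on the higher side Repin1 (2.96), Snrp1c-ps2 (2.96), Dynlrb1 (1.18), Mzf1 (2.60) and Ctbp2 (1.23). Cd4, Reg2, Chst3, Ciapin1, Uba7 and Mzf1 each had arrays under the floor, so their values depend on it. limma called 0 probe sets, with 142 at an unadjusted p under 0.05, and with the experiment as a block 0, with 258. Of the 22 lists 0 passed, but with the block DNA replication and S phase passed downward (median -0.31, adjusted p = 0.044, against 0.17 without the block). With an estimated correlation its value was an adjusted p = 0.74, and no list had a smaller one. It also passed without untreated 2 (-0.49, adjusted p = 0.00048), AzaC 1 (-0.51, adjusted p = 0.0016) or AzaC/TSA 2 (-0.38, adjusted p = 0.0088). Without untreated 2 the mitosis list passed downward (-0.34, adjusted p = 0.027), and without AzaC/TSA 2 the neural stem list upward (0.24, adjusted p = 0.021). The median half-width of the 95% interval was 1.31 without the block and 1.11 with it. Median centring moved the median of all probe sets from -0.033 to 0.145 and left the count at 0.

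Genes that are targets of the inhibitors or marks of cell identity were read in each comparison. Dnmt1, the maintenance DNA methyltransferase, fell with AzaC/TSA (-1.61, SE 0.30, adjusted p = 0.026; with the block 0.00391). With TSA its change was -1.04 (adjusted p = 0.0897), which passed only with the block (0.022), and with AzaC it was 0.05. The call with AzaC/TSA passed in 13 of 20 alternatives, with an adjusted p up to 0.22, and was lost without untreated 1 (0.0597), untreated 2 (0.22), AzaC/TSA 1 (0.134) or AzaC/TSA 2 (0.0838). Dnmt3a (0.02 with TSA, 0.84 with AzaC/TSA), Hdac1 (0.64 and 0.40) and Hdac2 (-0.26 and -0.35) did not pass. Neither did the cell cycle inhibitor Cdkn1a (0.45 and 0.89), which passed with AzaC/TSA in the blocked fit (0.0223), nor Bcl2 (0.04 and 0.43). A second probe set of Cdkn1a was also higher with both treatments. Its signals for experiments 1 and 2 were 1120.9 and 769.9 untreated, 2170.1 and 1174.1 with TSA, and 2806.4 and 1253.9 with AzaC/TSA. A second tested probe set of Bcl2 read 175.2 and 69.7 untreated, 185 and 71.5 with TSA, and 240.8 and 193.8 with AzaC/TSA. Whether the Bcl2 probe sets read the bcl2 transgene cannot be told from the arrays. Nes (-0.63 and 0.13), Gfap (0.70 and 0.77), Tubb3 (-0.81 and -0.77), Cd34 (0.76 and 0.88) and Kit (-0.76 and -1.22) did not pass either. The second, dimmer probe set of Tubb3 lay in the other direction with both treatments. Both Tubb3 probe sets are of the family kind. Dnmt3a, Gfap, Cd34 and Kit had arrays under the floor. Ptprc, a marker of white blood cells, had 3 probe sets with a highest signal of 19.2, under the floor of 20, and was not tested. Dnmt3b and H1f0 were not named on the array.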

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

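All tests in this part were chosen after the results they concern had been seen. The TSA effect differed between the experiments for 6 of 7987 probe sets by limma's test of the difference (TSA effect in experiment 2 minus that in experiment 1, with AzaC as a term). A2m, a protease inhibitor, went in opposite directions, with a TSA effect of 1.84 in experiment 1 and -1.52 in experiment 2 (difference -3.35, SE 0.28, adjusted p = 0.00399). Myo10 did the same, with 1.5 and -1.3 (-2.80, adjusted p = 0.0106). Akap12, a kinase anchoring protein, had 1.57 and 5.43 (3.87, adjusted p = 0.0106), the metallothionein Mt3 0.69 and 3.19 (2.51, adjusted p = 0.00937), and an unnamed probe set 4.15 and at least 8.61 (at least 4.46, adjusted p = 0.0106). Ccnd1 (cyclin D1) had -2.80 and -0.65 (2.15, adjusted p = 0.0441). Only 8 splits put 1 array of each group on each side, too few for a share under 0.05, and 2 of them gave as many probe sets (real value 6, highest other 578). That other split swaps the experiment numbers of the TSA-exposed arrays and so carries the difference between experiments. The highest of the remaining 6 splits was 1. These 6 leave all or part of the difference between experiments in the error, so their counts are no reference for the real value.

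The fall of mitosis genes with TSA was weighed against 2 technical sources. The list median kept a value of -2.92 or lower under quantile normalization and median centring. These moved the median of all probe sets only from 0.0144 to 0.0062 and -0.0489, so they could hardly have moved the list. Each also takes the overall signal of the arrays as equal, so a difference in overall signal was not tested. Relative to the other probe sets the list was lower under each scaling. Dilution by cells without neural stem transcripts would lower the neural stem list by about as much, but its lower quartile was -0.35. No biological explanation was tested.

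MHC class I signals were higher in experiment 2 (median of 15 genes 0.41; 3 passed, 4 adjusted over the list alone; camera adjusted p = 0.0096, and adjusted p = 0.50 with an estimated correlation). Cross-hybridisation among family members cannot be the whole cause, since B2m and Tap1, which are not of the family kind, were both higher, with 1.18 (Tap1) the smaller difference. Blood cells in the cultures of experiment 2 would bring their abundant transcripts, but no probe set of Ptprc, Coro1a, Cd53 or Laptm5, genes of white blood cells, was higher by more than 17.6 in any group, against 1649.5 to 3648.9 for B2m (blood list median -0.26). The signals of Cd52 and Hba-a1, also of blood cells, were higher by up to 100.3 and 106.4 in groups with TSA. With AzaC alone Cd52 was higher by 47.5, while Hba-a1 differed by -22.2. In untreated cells, where B2m differed most, Cd52 and Hba-a1 differed by -13.8 and -27.1. Together these values argue against blood cells as the whole source, most directly in untreated cells. Interferon signalling could raise class I transcripts. The interferon list did not pass (median 0.30). Of its 10 members 1 passed by limma, Ifi27 (1.70, adjusted p = 0.00137), higher in all 4 groups. This leaves interferon signalling open. An untested difference in the genotype of the embryos is open too.

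That AzaC gave 0 calls (175 at an unadjusted p under 0.05 by limma) was weighed against experiment differences that inflate the error. With the experiment as a block, which raised the TSA count from 401 to 971, 328 probe sets had an unadjusted p under 0.05, below the 399 that chance gives, and 0 passed. Taking out the differences that all groups shared thus gave no calls. Differences between experiments that vary by group stay in the error, so the block cannot judge them. AzaC averaged over TSA, with the experiment as a term, had 447 by limma at an unadjusted p under 0.05. That is above 399, and 0 passed. Whether 500 nM for 2 days lowered DNA methylation in these cells cannot be read from the arrays, and no biological explanation was tested.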

How the results depend on the processing

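The alternatives were planned except for the added comparisons. No named gene or list that passed, in the results or under an alternative, changed its direction. Called probe sets of other genes were not checked for this. Of all values under an alternative, 136 of 12372 gene values and 126 of 1848 list medians changed sign, and 0 of these passed in either fit. The balance of higher and lower calls turned only for AzaC/TSA against AzaC with median centring, as given in the results. Without the filter on dim probe sets the counts were 135 for TSA, 63 for AzaC/TSA and 113 for AzaC/TSA against AzaC, and 13 for AzaC, 11 for AzaC/TSA against TSA and 11 for the interaction, where the reported count was 0. More probe sets are tested without the filter, and the cause of the calls that appear was not tested. Without the intensity trend the counts were 216 for TSA, 152 for AzaC/TSA, 135 for AzaC/TSA against AzaC and 1 for the interaction. With only the groups compared, which leaves fewer arrays to estimate the spread, they were 176, 49 and 45. The replicate block gave 971, 746 and 744. Leaving out each array in turn gave 56 to 367 for TSA, 14 to 223 for AzaC/TSA, 48 to 158 for AzaC/TSA against AzaC, and 0 for the 3 others. Quantile normalization, median centring, no scaling, the other floors, the offset, the filter at 50% and robust eBayes kept each count within 1.5 times. No scaling changed no count, since the arrays had been scaled. Of 12372 values of named genes under an alternative, 445 lost and 65 gained a call. Of 1848 values of lists, 21 lost and 28 gained one. The 18 list calls in the 3 comparisons with calls were lost with an estimated correlation, and otherwise kept under their other alternatives, except for the p53 targets and the histones with AzaC/TSA as given in the results. For TSA against AzaC, a comparison added after seeing the data, limma called 415 probe sets (185 higher, 230 lower), and 1122 with the block. Signal over background limits what can be read: 23.9% to 30% of probe sets per array lay under the floor.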

Other observations

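The comparison of the experiments and the average over AzaC exposure, with their tests, were chosen after the data had been seen, as were the genes named in this part. The cultures of the 2 experiments differed in single genes. In experiment 2 the glutamate receptor subunit Gria2 (-2.59, SE 0.22, adjusted p = 0.00046), the adhesion protein Cntn1 (-3.13, SE 0.31, adjusted p = 0.00136), Thy1 (-3.21, at least), the imprinted gene Nnat (-3.24), the growth factor Gas6 (-3.63, at least) and Apoe (-2.59) were lower on the log2 scale. The phospholipid-binding protein Anxa1 (at least 4.37, SE 0.34, adjusted p = 0.00037), aldolase C (Aldoc, 1.94), the hexokinase Hk2 (1.62), the pyruvate dehydrogenase kinase Pdk1 (1.52), and the antigen presentation genes H2-K2 (2.5), H2-D1 (1.74) and B2m (1.41) were higher. The probe sets of Anxa1, H2-K2 and H2-D1 are of the family kind. limma called 337 of 7987 probe sets, 126 higher and 211 lower in experiment 2, of which 334 went the same way in all 4 groups. Only 8 splits of the arrays put 1 array of each group on each side, too few for a share under 0.05 (1 of 8 as large; real value 337, highest other 0). The other balanced splits leave all or part of the difference between the experiments in the error, so their 0 is no reference for the 337. The same holds for the other 24 splits that the model could fit.

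By list, 3 of 25 neuronal genes were lower in experiment 2 (Cntn1, Gria2 and Chgb, -1.41; 3 adjusted over the list alone; camera adjusted p = 0.15). Of 12 astrocyte genes 1 was higher and 3 were lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.56). DNA replication genes were higher by a median of 0.41 (3 of 35 passed, 4 adjusted over the list alone; camera adjusted p 1e-04), with Mcm3 (1.32), Mcm2 (0.90) and Pcna (0.86), and mitosis genes by 0.35 (1 of 35, Mad2l1 with 0.98, also adjusted over the list alone; 9.9e-05). The replication list had an adjusted p = 0.50 with an estimated correlation, and the mitosis list an adjusted p = 0.48 with an estimated correlation. Whether each experiment used other embryos is not given in the sources used here.

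AzaC averaged over TSA exposure, 4 arrays against 4, gave 0 probe sets past the threshold by limma (smallest adjusted p 0.407). At an unadjusted p under 0.05 there were 447, above the 399 that chance gives. Only 8 splits keep TSA exposure and experiment balanced, too few for a share under 0.05, and with a real value of 0 each gives at least as many by construction (8 of 8; highest other 0). Apoe, the main lipid carrier of glia, was the named gene of smallest p without passing (1.79, SE 0.35, adjusted p = 0.718). Its signal was 2633 and 237 on the untreated arrays, 3895 and 1831 with AzaC, 4133 and 307 with TSA, and 8117 and 1949 with AzaC/TSA, each for experiments 1 and 2.

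Cd34, a surface marker of blood progenitors and endothelium, had 2 tested probe sets. The brighter read 27.9 and 7 on the untreated arrays, 40.2 and 5.9 with AzaC, 79.5 and 8.3 with TSA, and 95 and 18.3 with AzaC/TSA, for experiments 1 and 2. The other read 6.1 and 2, 10.4 and 8.3, 64 and 11.6, and 93.7 and 5.8 in the same order. All values of experiment 2 lay under the floor of 20, and no test of Cd34 passed.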
